A study of Mus musculus with 21 samples.

How the data were processed

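The samples were 21 RNA-seq libraries of mouse Ly6C+/Sca-1+ fibroblasts, made from total RNA with a stranded kit. The deposited table holds raw counts per gene made by the authors, 52636 genes by 21 libraries, and the aligner, the counter, their versions, the strand setting and any filter are not given in the sources used here. The submitters name the builds GRCh38 and GRCm38 without saying what each was for, and the gene IDs are mouse Ensembl IDs. Of these, 52489 are in the GENCODE M21 annotation of GRCm38, from which symbols and positions were taken, and 233, with 0.0192% of the counts, had no name. All 21 single-library tables were checked and equalled their column of the table of all libraries. Groups were taken from the labels. Replicate numbers follow the order of the records and pair nothing, so libraries were not paired.

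Library totals are given with the data, and each group had 3 libraries. Genes passing filterByExpr with default settings were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, a design with 1 coefficient per group over all 21 libraries, and robust quasi-likelihood F-tests (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.0581. The interaction was the CHIR effect with TGFb1 less that without it. A gene with 0 counts in every library of a group was given a fold only as a bound, against 3 counts over the group. The limma 3.58.1 camera test was run on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, and fry was run beside it. The 30 lists were fixed before the data were examined, as were the comparisons, the alternatives planned and the rule for naming genes.

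By that rule, each of 5 main comparisons names the 8 genes with the highest and the 8 with the lowest log2 fold change among those past the threshold, with a mean of at least 2 log2 CPM over all libraries, no overlap between the groups, and no predicted, clone or RIKEN name. Chance gives no overlap for 10% of genes with 3 against 3. The other comparisons name 4 per direction, without the rule on overlap for the interaction. Up to 4 members are named per list, and 12 genes were fixed by name; some genes that these rules name are not reported here. Genes for which reads shared with near-identical copies appear to be left out were avoided where the text could do so: in this table Gapdh held 45 counts in all libraries together.

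The fit was tested on simulated data in each comparison with 80 genes changed 1.5-fold, 60 changed 2-fold and 60 changed 4-fold. The genes recovered were 57, 54 and 60, with 6 others called for TGFb1 + DMSO against DMSO. They were 71, 58 and 59, with 6 others called for CHIR against DMSO and 62, 53 and 60, with 11 others called for TGFb1 + CHIR against TGFb1 + DMSO. For TGFb1 + CHIR against CHIR they were 59, 55 and 60, with 8 others called, for IL1b 67, 56 and 60, with 7 others called, and for TNF 69, 56 and 59, with 4 others called. For IL1b against TNF they were 64, 51 and 60, with 12 others called, for the solvent 59, 57 and 60, with 8 others called, and for the interaction 52, 56 and 60, with 12 others called.

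The alternatives were DESeq2 1.42.0, limma voom, RLE factors, no filter, a stricter filter (1 CPM in at least 3 libraries), mitochondrial and rRNA genes left out, only the groups of the comparison in the fit, the other TGFb1 control, and each replicate left out in turn. For the overlap of the IL1b and TNF responses, leaving out replicates was chosen after seeing the data. Other splits of the libraries were fitted with only the groups of the comparison. Left out were pathway databases, none of which was available, and splicing, which gene counts do not hold.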

Results

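Stranded total RNA-seq was done on fibroblasts from mouse lung that carry Ly6C and Sca-1, cell-surface proteins (Sca-1 is encoded by Ly6a). The cells were stimulated in culture with TGFb1, a cytokine that drives fibroblasts to make matrix, with CHIR, with the inflammatory cytokines IL1b or TNF added to TGFb1, or with DMSO, a solvent. The labels give CHIR by that short name only; it commonly stands for an inhibitor of GSK3, a kinase that marks beta-catenin for breakdown in the Wnt pathway. Doses, times and whether the replicates were separate cultures or animals are not given in the sources used here. The 21 libraries form 7 groups with 3 replicates each. The CHIR libraries held 26926130, 26431985 and 20575669 counts. The DMSO libraries held 28176095, 28441137 and 23546115 counts. The TGFb1 libraries held 26516043, 28445604 and 19796379 counts. The TGFb1 + CHIR libraries held 27939699, 20996190 and 20405826 counts. The TGFb1 + DMSO libraries held 25767384, 29276382 and 27205028 counts. The TGFb1 + IL1b libraries held 27747521, 28279598 and 28217964 counts. The TGFb1 + TNF libraries held 26404529, 27273505 and 25609647 counts. The p-values below measure the spread between these libraries only, and floors and counting intervals cover counting error only.

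The 3 libraries of each group lay together in a principal component analysis, in which component 1 held 55.6% of the variance and parted the groups with TGFb1 from those without it, and component 2 held 14.5%. Mitochondrial genes took 1.04 ± 0.11% of the counts (mean ± SD, n = 3) in CHIR, 0.572 ± 0.017% in DMSO, 0.35 ± 0.048% in TGFb1 and 0.511 ± 0.049% in TGFb1 + CHIR. The summed level of the immune cell markers ran from 9.53 ± 1.27 CPM (library-size scaled counts, mean ± SD, n = 3) in TGFb1 + CHIR to 20.2 ± 1.94 in DMSO. That of the epithelial markers ran from 1.22 ± 0.0895 in CHIR to 5.15 ± 1.07 in TGFb1 + IL1b. That of the endothelial markers ran from 7.92 ± 1.18 in TGFb1 to 26 ± 1.09 in TGFb1 + CHIR, where Kdr was the highest member. The mesothelial markers summed to 9.16 ± 0.496 CPM in CHIR and 27.7 ± 0.563 in TGFb1 + IL1b, nearly all of it Wt1. The mural and smooth muscle markers, led by Pdgfrb, which fibroblasts also express, ran from 525 ± 13.1 CPM in TGFb1 + TNF to 1285 ± 17.2 in CHIR.

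**Figure D1:**
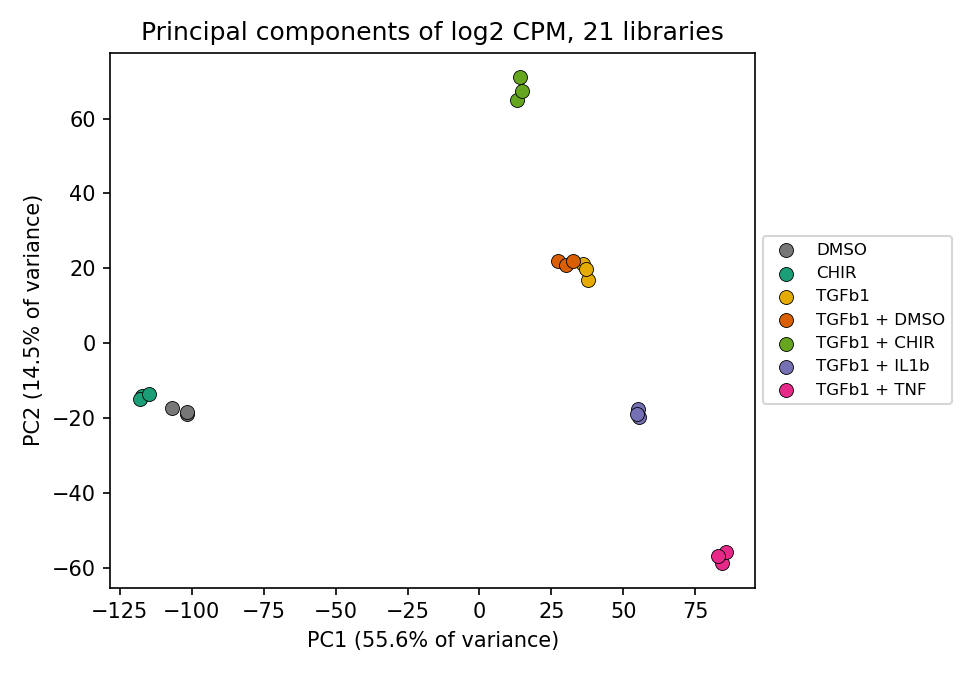
Principal components 1 (x axis) and 2 (y axis) of the log2 CPM of the genes tested, in units of the component score, with 1 point per library coloured by group. Libraries with TGFb1 lie apart from those without it along component 1.

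Of the genes chosen before the data were examined to be given in every group, Col1a1, a chain of type I collagen (ENSMUSG00000001506 on chromosome 11 from 94936224 to 94953042, GRCm38), stood at 12560 ± 142 CPM in DMSO, 27720 ± 903 in TGFb1, 34040 ± 2180 in TGFb1 + CHIR and 11300 ± 378 in TGFb1 + TNF (mean ± SD, n = 3). Acta2, the smooth muscle actin of myofibroblasts (ENSMUSG00000035783 on chromosome 19 from 34241090 to 34255590), stood at 1114 ± 37, 2392 ± 42, 1018 ± 14 and 901 ± 72.2 CPM in the same groups. Axin2, a Wnt target (ENSMUSG00000000142 on chromosome 11 from 108920349 to 108950783), was at 5 ± 1.05 CPM in DMSO, 18.6 ± 0.584 in CHIR and 70.8 ± 1 in TGFb1 + CHIR. Saa3, an acute phase protein gene (ENSMUSG00000040026 on chromosome 7 from 46711998 to 46715700), was at 0.156 ± 0.164 CPM in TGFb1 and 14.3 ± 1.88 in TGFb1 + IL1b. Ly6a (ENSMUSG00000075602 on chromosome 15 from 74994877 to 74998031) was at 142 ± 5.52 CPM in DMSO and 7.83 ± 0.949 in TGFb1 + CHIR, and Ly6c1 (ENSMUSG00000079018 on chromosome 15 from 75044018 to 75048830) at 49.8 ± 1.77 and 0.703 ± 0.128. Ly6c1 has a close copy beside it, Ly6c2, and how reads shared by both were counted is not given in the sources used here. The plot of these genes by group shows every library.

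**Figure D2:**
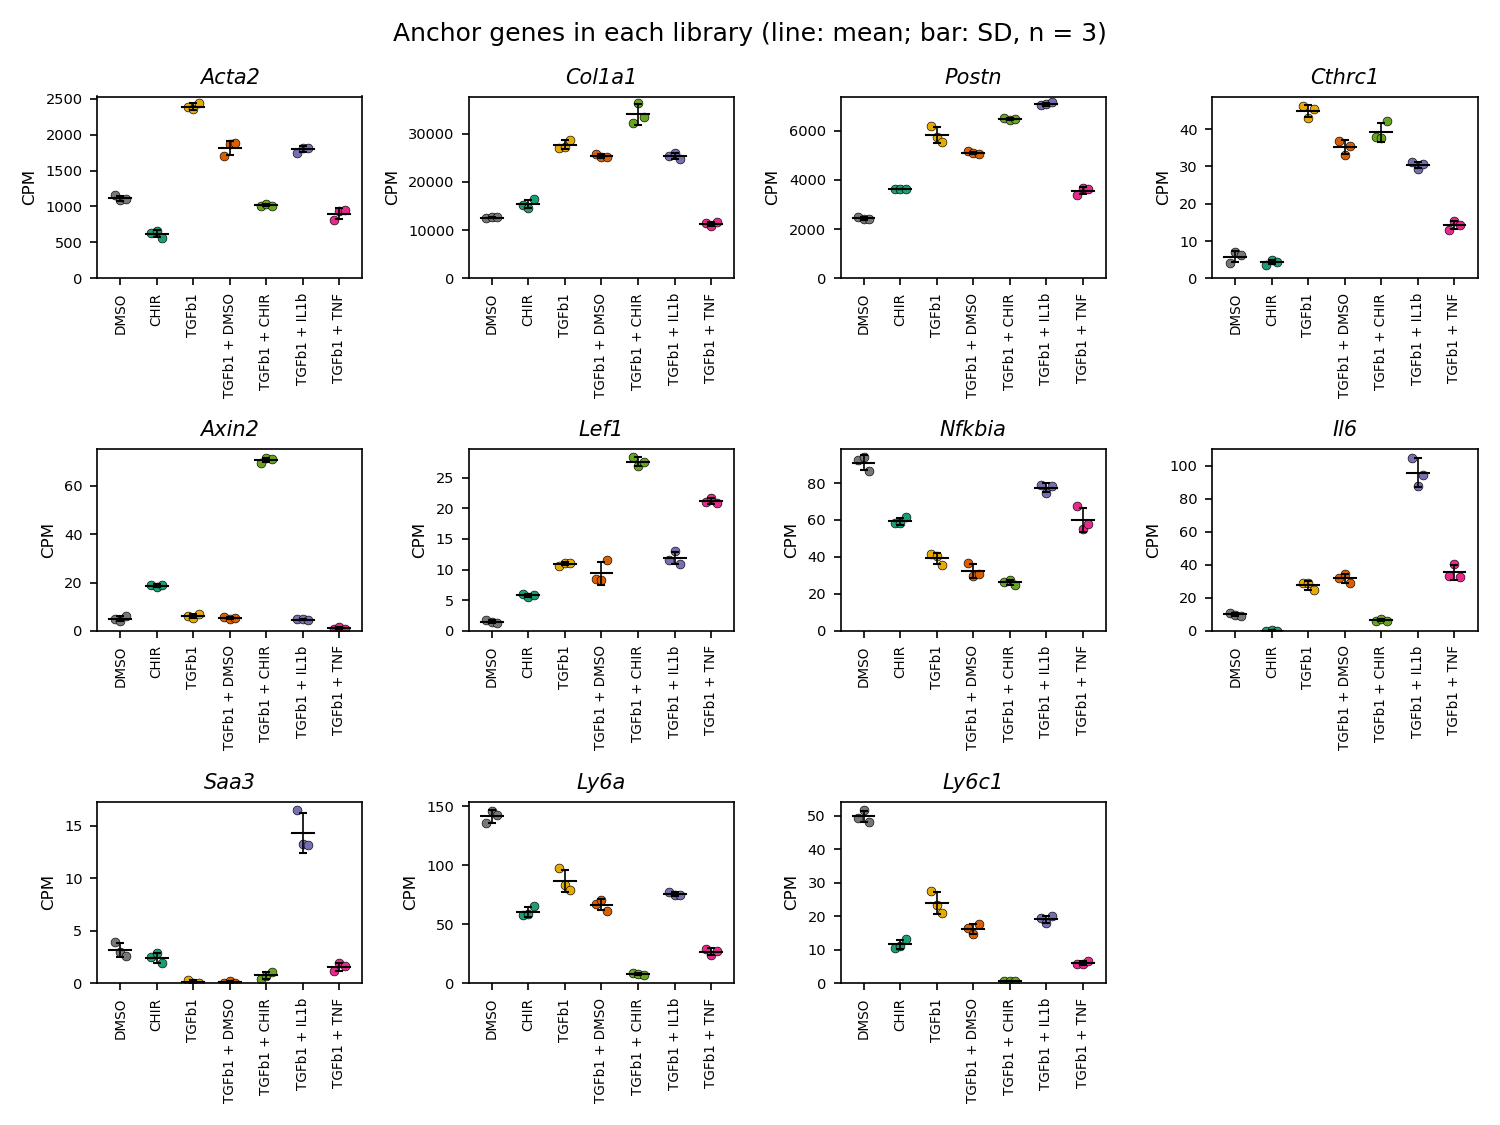
Level of each of 11 of these genes (y axis, CPM) in the 7 groups (x axis), with 1 point per library, the group mean as a line and the SD as a bar. Axin2 is highest in TGFb1 + CHIR and Saa3 in TGFb1 + IL1b.

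Below, values in parentheses after a gene are its log2 fold change ± SE from the edgeR fit (n = 3 per group), and medians of lists are of log2 fold changes, positive where the group named before "against" is higher. Counts of list members adjusted over the list alone equalled those adjusted over all genes tested wherever no separate count is given. A camera call printed without a p for an estimated correlation also passed with one.

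TGFb1 + DMSO against DMSO asked what TGFb1 does to these fibroblasts in the presence of the solvent. Matrix and TGFb target genes rose: Cthrc1, a secreted protein of matrix-producing fibroblasts, rose 6.11-fold (2.61 ± 0.11, adjusted p = 6.91e-27). Postn, a matricellular protein, rose 2.09-fold (1.06 ± 0.035) and Col1a1 2.02-fold (1.01 ± 0.037). Complement and acute phase genes fell, with C3, the central complement component, 50.1-fold lower (-5.65 ± 0.06). Anxa8, a calcium-dependent membrane-binding annexin (gene ID ENSMUSG00000021950, GRCm38 chromosome 14, 34085981 to 34100571), rose most of the genes that met the rule for naming, from 0.056 ± 0.0969 to 73.9 ± 5.95 CPM (10.16 ± 0.24). Also among the highest were Acsbg1, an acyl-CoA synthetase, Abcb1a, a drug efflux pump, AA467197, Gpr35, Lrrc15 and Col8a2, which rose by 7.65 to 6.23. Tnxb, the matrix glycoprotein tenascin X (gene ID ENSMUSG00000033327, GRCm38 chromosome 17, 34670535 to 34719815), fell most, from 629 ± 31.8 to 3.9 ± 0.259 CPM (-7.33 ± 0.17), followed by Clu (-7.30 ± 0.13), Abi3bp (-6.62 ± 0.13), Atp1b1 (-6.46 ± 0.10), Cxcl1 (-6.29 ± 0.20), Selenop (-6.18 ± 0.077), Vegfd (-5.98 ± 0.075) and Pamr1 (-5.70 ± 0.062). Among these, Clu encodes the chaperone clusterin, Cxcl1 a neutrophil chemokine, Selenop a selenium carrier and Vegfd a lymphatic growth factor.

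Of the 27 fibrillar collagen and matrix genes tested, 24 rose and 3 fell. The median was 1.06 (camera adjusted p = 1.3e-09), with Vcan at 2.87 ± 0.048 and Col6a2 at -2.34 ± 0.05. Among 22 collagen processing and crosslinking genes, 18 rose, 3 fell and 1 did not pass. The median was 1.04 (camera adjusted p = 3.21e-07), with Loxl2 at 2.16 ± 0.039 and Adamts2 at -1.95 ± 0.039. For the TGFb and SMAD target genes, 16 rose, 3 fell and 1 did not pass of 20 tested. The median was 1.55 (camera adjusted p = 3.11e-08), with Il11 at 4.89 ± 0.31, Ccn2 at 3.56 ± 0.068 and Pmepa1 at 3.55 ± 0.042. Across 22 contractile and myofibroblast genes, 13 rose, 7 fell and 2 did not pass. The median was 0.38 (camera adjusted p = 0.023, and adjusted p = 0.325 with an estimated correlation), with Itga5 at 2.48 ± 0.037 and Cnn1 at 1.60 ± 0.068. For TGFb1 against DMSO, 14 rose and 4 fell (median 0.67). Of the 11 ID family and BMP target genes tested, 2 rose, 8 fell and 1 did not pass. The median was -2.19 (camera adjusted p = 0.00118), with Id1 at -3.96 ± 0.20, Id4 at -3.49 ± 0.12 and Atoh8 at -3.22 ± 0.12, genes raised by the related BMP ligands. Among 24 Wnt and beta-catenin target genes, 10 rose, 11 fell and 3 did not pass. The median was 0.10 (camera adjusted p = 0.495, adjusted over the list alone, 11 rose and 11 fell), with Lgr6 at 5.43 ± 0.18, Ccn4 at 3.39 ± 0.042 and Tnfrsf19 at -2.91 ± 0.19. In TGFb1 against DMSO, 11 rose and 8 fell (median 0.18). Axin2 was at 0.10 ± 0.14 (adjusted p = 0.567).

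All 28 tested cell cycle genes rose. The median was 1.06 (camera adjusted p = 1.23e-10), with Ccne1 at 2.13 ± 0.12 and Bub1 at 1.63 ± 0.076. Among 18 secretory pathway and unfolded protein genes, 17 rose, 0 fell and 1 did not pass. The median was 0.77 (camera adjusted p = 3.11e-08), with Hyou1 at 1.13 ± 0.043 and Hspa5 at 1.07 ± 0.042. For the glycolysis and hypoxia genes, 17 rose, 1 fell and 1 did not pass of 19 tested. The median was 1.87 (camera adjusted p = 1.65e-08), with Egln3 at 2.41 ± 0.10 and Adm at -3.60 ± 0.11. Among 18 ATF4, serine and proline synthesis genes, 16 rose and 2 fell. The median was 0.91 (camera adjusted p = 3.21e-07, and adjusted p = 0.136 with an estimated correlation), with Pycr1 at 1.69 ± 0.06 and Asns at 1.48 ± 0.041. For the sterol synthesis genes, 17 rose and 3 fell of 20 tested. The median was 0.66 (camera adjusted p = 7.42e-05, and adjusted p = 0.136 with an estimated correlation), with Mvd at 0.99 ± 0.079. Among 15 p53 and apoptosis genes, 9 rose, 4 fell and 2 did not pass. The median was 0.39 (camera adjusted p = 0.023), with Pmaip1 at 3.87 ± 0.10 and Cdkn1a at 1.73 ± 0.075.

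All 13 tested acute phase and complement genes fell. The median was -3.98 (camera adjusted p = 4.15e-09), with Hp at -6.78 ± 0.24 and C3 at -5.65 ± 0.06. Among 15 chemokine genes, 3 rose, 10 fell and 2 did not pass. The median was -1.75 (camera adjusted p = 0.00121), with Cxcl1 at -6.29 ± 0.20 and Ccl9 at -3.64 ± 0.15; Cxcl13, a B cell chemokine, was listed at 0 in TGFb1 + DMSO and thus at least 109-fold lower. For TGFb1 against DMSO, 3 rose and 10 fell (median -1.45, adjusted p = 0.0599 with an estimated correlation). For the NF-kB feedback and target genes, 4 rose, 14 fell and 4 did not pass of 22 tested. The median was -0.46 (camera adjusted p = 0.0246), with Nfkbia at -1.49 ± 0.071 and Vcam1 at -1.40 ± 0.043. In TGFb1 against DMSO, 5 rose and 13 fell (median -0.42, camera adjusted p = 0.0757, adjusted p = 0.104 with an estimated correlation). Across 25 cytokine and growth factor genes, 7 rose, 11 fell and 7 did not pass. The median was -0.39, or -0.16 with genes at 0 in a group set to their bound (camera adjusted p = 0.673), with Il11 at 4.89 ± 0.31, Il33 at -4.16 ± 0.26 and Fgf7 at -3.03 ± 0.073. For TGFb1 against DMSO, 8 rose and 11 fell (median -0.19). Among 30 interferon-stimulated genes, 21 rose, 2 fell and 7 did not pass. The median was 1.09 (camera adjusted p = 0.00179, and adjusted p = 0.497 with an estimated correlation), with Rsad2 at 4.69 ± 0.48 and Oasl1 at 4.62 ± 0.27. In TGFb1 against DMSO, 11 rose and 3 fell (median 0.45, camera adjusted p = 0.118). For the antigen presentation genes, 2 rose, 10 fell and 3 did not pass of 15 tested. The median was -0.75 (camera adjusted p = 0.0246, and adjusted p = 0.285 with an estimated correlation), with Cd74 at 1.63 ± 0.12 and Nlrc5 at -1.43 ± 0.13. Of the 18 immediate early and heat shock genes tested, 4 rose, 13 fell and 1 did not pass. The median was -1.69 (camera adjusted p = 0.000713, and adjusted p = 0.285 with an estimated correlation), with Fosb at -4.63 ± 0.17, Fos at -3.44 ± 0.17 and Nr4a1 at -2.88 ± 0.21.

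Among 11 alveolar fibroblast marker genes, 2 rose, 8 fell and 1 did not pass. The median was -2.08 (camera adjusted p = 0.00133), with Itga8 at -4.93 ± 0.29 and Limch1 at -4.38 ± 0.15, and Ces1d, a lipid esterase, at least 299-fold lower. For the adventitial fibroblast marker genes, 6 rose, 12 fell and 1 did not pass of 19 tested. The median was -0.60 (camera adjusted p = 0.0984), with Clec3b at -6.44 ± 0.41 and Dcn at -3.29 ± 0.044. For TGFb1 against DMSO, 9 rose and 10 fell (median -0.28). Across 14 adipogenic and lipid genes, 5 rose, 8 fell and 1 did not pass. The median was -0.60 (camera adjusted p = 0.401), with Apoe at -6.49 ± 0.15 and Lpl at -2.41 ± 0.05. Among 26 matrix protease and inhibitor genes, 10 rose, 13 fell and 3 did not pass. The median was -0.19 (camera adjusted p = 0.581), with Mmp13 at 3.84 ± 0.15 and Adamts15 at -4.17 ± 0.11. For the prostaglandin and oxidative response genes, 7 rose, 6 fell and 1 did not pass of 14 tested. The median was 0.16 (camera adjusted p = 0.673), with Ptgs1 at 0.98 ± 0.041 and Ptger4 at -1.55 ± 0.12. Of the 10 mitochondrially encoded genes tested, 0 rose, 5 fell and 5 did not pass. The median was -0.49 (camera adjusted p = 0.0781), with mt-Nd4 at -0.58 ± 0.13 and mt-Co1 at -0.55 ± 0.11. In TGFb1 against DMSO, 0 rose and 8 fell (median -0.67, camera adjusted p = 0.0211, and adjusted p = 0.432 with an estimated correlation).

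By the edgeR quasi-likelihood test, 10037 of the 16197 genes tested passed (4973 higher, 5064 lower). Of them, 1307 were at least 2-fold higher and 2224 at least 2-fold lower. Of the lists, 18 of 30 passed the camera test (11 higher, 7 lower) and 12 passed with an estimated correlation. DMSO without TGFb1 was the only control with solvent alone, so TGFb1 is compared here within the solvent.

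**Figure D3:**
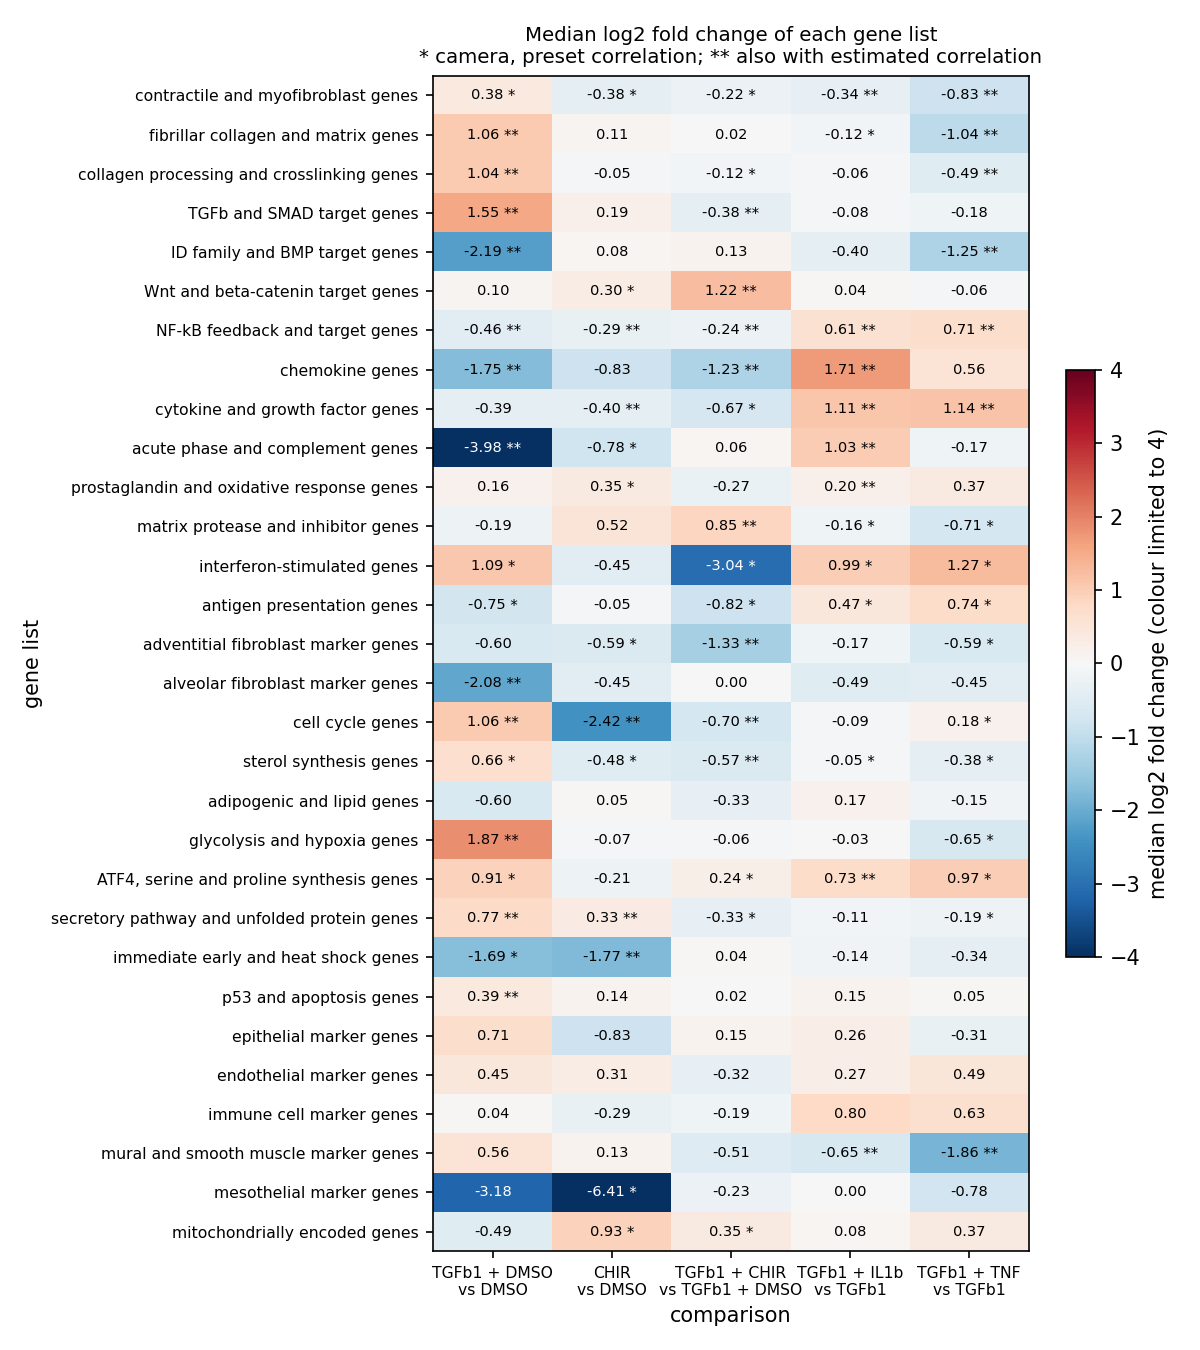
Median log2 fold change (colour scale) of each of the 30 gene lists (y axis) in the 5 main comparisons (x axis). A single star marks a camera call and a double star a call that also passed with an estimated correlation; cell cycle genes rose with TGFb1 + DMSO and fell with CHIR.

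CHIR against DMSO asked what CHIR does without TGFb1. Immediate early genes and cell cycle genes fell. Fosb and Fos, which encode AP-1 transcription factor subunits, fell 240-fold (-7.91 ± 0.22, adjusted p = 5.37e-14) and 203-fold (-7.66 ± 0.23, adjusted p = 9.68e-14), Fos from 1517 ± 112 to 7.45 ± 0.842 CPM (gene ID ENSMUSG00000021250, GRCm38 chromosome 12, 85473890 to 85477273). Axin2 rose 3.75-fold (1.91 ± 0.12) and Lef1, a transcription factor partner of beta-catenin, 3.88-fold (1.96 ± 0.16). After Fosb and Fos, the lowest were Il6 (-5.90 ± 0.24), Zfp36 (-5.35 ± 0.14), Btg2 (-4.99 ± 0.17), Junb (-4.92 ± 0.10), Cxcl1 (-4.91 ± 0.18) and Egr1 (-4.71 ± 0.12); Il6 encodes an inflammatory cytokine and Zfp36 a protein that speeds mRNA decay. Igfbp5, which binds insulin-like growth factors (gene ID ENSMUSG00000026185, GRCm38 chromosome 1, 72857932 to 72874884), rose most, from 58.6 ± 2.85 to 490 ± 34.5 CPM (3.06 ± 0.12), followed by Col15a1 (2.90 ± 0.072), Lrrc15 (2.81 ± 0.32), Megf10 (2.80 ± 0.084), Mamdc2 (2.27 ± 0.11), Mmd (2.21 ± 0.10) and Olr1 (2.15 ± 0.089). Col15a1 encodes a basement membrane zone collagen and Olr1 a receptor for oxidised lipoprotein. Col1a1 (0.29 ± 0.037) and Postn (0.57 ± 0.035) rose, while Acta2 (-0.85 ± 0.049) fell and Saa3 was at -0.38 ± 0.26 (adjusted p = 0.245).

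Of the 18 immediate early and heat shock genes tested, 0 rose, 16 fell and 2 did not pass. The median was -1.77 (camera adjusted p = 3.73e-14), with Fosb at -7.91 ± 0.22, Fos at -7.66 ± 0.23, Junb at -4.92 ± 0.10 and Egr1 at -4.71 ± 0.12. All 28 tested cell cycle genes fell. The median was -2.42 (camera adjusted p = 7.99e-28), with Ccnb1 at -3.23 ± 0.23, Rrm2 at -3.06 ± 0.11, Plk1 at -3.04 ± 0.11 and Mki67 at -3.02 ± 0.10. Among 24 Wnt and beta-catenin target genes, 14 rose, 5 fell and 5 did not pass. The median was 0.30 (camera adjusted p = 0.0176, and adjusted p = 0.0502 with an estimated correlation), with Lgr6 at 2.06 ± 0.27, Lef1 at 1.96 ± 0.16 and Ccnd1 at -2.10 ± 0.081. For the NF-kB feedback and target genes, 2 rose, 15 fell and 5 did not pass of 22 tested. The median was -0.29 (camera adjusted p = 0.00285), with Nfkbiz at -3.48 ± 0.10 and Zc3h12a at -1.86 ± 0.093. Across 25 cytokine and growth factor genes, 2 rose, 15 fell and 8 did not pass. The median was -0.40 (camera adjusted p = 0.000726), with Il6 at -5.90 ± 0.24, Lif at -2.21 ± 0.11 and Tslp at -2.18 ± 0.28. Among 15 chemokine genes, 2 rose, 6 fell and 7 did not pass. The median was -0.83, or 0 with genes at 0 in a group set to their bound (camera adjusted p = 0.117), with Cxcl1 at -4.91 ± 0.18 and Ccl2 at -1.53 ± 0.086. For the acute phase and complement genes, 2 rose, 9 fell and 2 did not pass of 13 tested. The median was -0.78 (camera adjusted p = 0.0325, and adjusted p = 0.188 with an estimated correlation), with Ptx3 at -2.25 ± 0.095. Of the 22 contractile and myofibroblast genes tested, 5 rose, 16 fell and 1 did not pass. The median was -0.38 (camera adjusted p = 0.00131, and adjusted p = 0.188 with an estimated correlation, adjusted over the list alone, 5 rose and 17 fell), with Fhl2 at -1.76 ± 0.063 and Acta2 at -0.85 ± 0.049.

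Among 27 fibrillar collagen and matrix genes, 17 rose, 9 fell and 1 did not pass. The median was 0.11 (mean -0.18, test directed upward, camera adjusted p = 0.356), with Col8a1 at -2.57 ± 0.079 and Col12a1 at -2.08 ± 0.041. For the TGFb and SMAD target genes, 10 rose, 7 fell and 3 did not pass of 20 tested. The median was 0.19 (mean -0.20, test directed upward, camera adjusted p = 0.302), with Junb at -4.92 ± 0.10. Among 20 sterol synthesis genes, 0 rose, 17 fell and 3 did not pass. The median was -0.48 (camera adjusted p = 1.24e-07, and adjusted p = 0.0727 with an estimated correlation), with Mvk at -1.04 ± 0.092. Across 18 secretory pathway and unfolded protein genes, 14 rose, 0 fell and 4 did not pass. The median was 0.33 (camera adjusted p = 1.85e-06), with Atf6 at 0.77 ± 0.054 and Hyou1 at 0.55 ± 0.043. Among 14 prostaglandin and oxidative response genes, 9 rose, 3 fell and 2 did not pass. The median was 0.35 (mean -0.11, test directed upward, camera adjusted p = 0.0325, and adjusted p = 0.0727 with an estimated correlation), with Gclc at 1.08 ± 0.056 and Ptgs2 at -2.11 ± 0.12. Of the 19 adventitial fibroblast marker genes tested, 5 rose, 10 fell and 4 did not pass. The median was -0.59 (camera adjusted p = 0.0461, and adjusted p = 0.188 with an estimated correlation, adjusted over the list alone, 5 rose and 11 fell), with Col15a1 at 2.90 ± 0.072 and Ly6c1 at -2.10 ± 0.10. All 10 tested mitochondrially encoded genes rose. The median was 0.93 (camera adjusted p = 2.82e-05, and adjusted p = 0.188 with an estimated correlation), with mt-Nd4 at 1.03 ± 0.13 and mt-Cytb at 0.98 ± 0.12.

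Beside the fibrillar collagen, TGFb target, chemokine and protease lists, these did not pass the camera test: collagen processing and crosslinking genes, ID family and BMP target genes, interferon-stimulated genes, antigen presentation genes, alveolar fibroblast markers, adipogenic and lipid genes, glycolysis and hypoxia genes, ATF4, serine and proline synthesis genes, p53 and apoptosis genes, and the epithelial, endothelial, immune and mural markers. In the edgeR test, 7260 of the 16197 genes tested passed (3578 higher, 3682 lower). Of them, 436 were at least 2-fold higher and 986 at least 2-fold lower. Of the lists, 13 of 30 passed the camera test (4 higher, 9 lower) and 5 passed with an estimated correlation. 

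**Figure D4:**
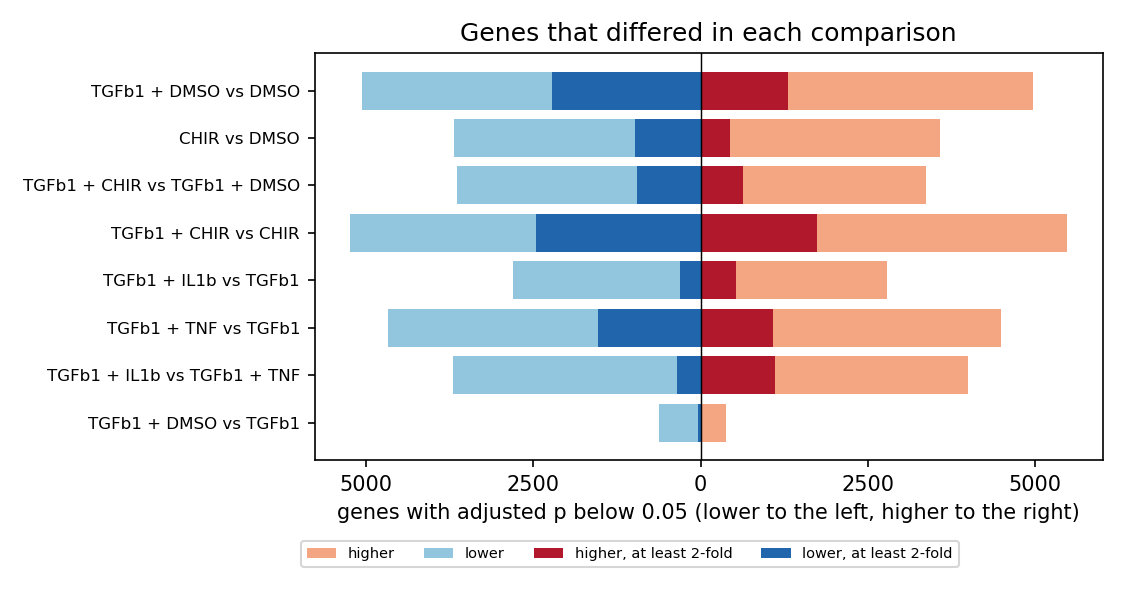
Number of genes (x axis) lower, to the left, and higher, to the right, at an adjusted p under 0.05 in each comparison (y axis), with the part that changed at least 2-fold in the darker colour. TGFb1 + DMSO against TGFb1 has the fewest, 993.

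TGFb1 + CHIR against TGFb1 + DMSO asked what CHIR does in cells given TGFb1. Wnt targets and matrix proteases rose, while adventitial fibroblast markers and part of the TGFb targets fell. All 30 interferon-stimulated genes fell too, though as a list they did not pass with an estimated correlation (adjusted p = 0.0714). Mmp13, a collagen-cutting protease (gene ID ENSMUSG00000050578, GRCm38 chromosome 9, 7272514 to 7283331), rose 28.9-fold, from 89 ± 6.26 to 2570 ± 204 CPM (4.85 ± 0.12, adjusted p = 5.46e-15), and Axin2 rose 13.3-fold (3.74 ± 0.12). Hsd11b1, which makes active glucocorticoid, rose most (5.86 ± 0.36; gene ID ENSMUSG00000016194, GRCm38 chromosome 1, 193221634 to 193264075), and the others among the highest were Osr2 (4.83 ± 0.14), Nkd2 (4.68 ± 0.089), Igfbp3 (4.43 ± 0.05), Adamts15 (4.31 ± 0.11), Tnfrsf19 (4.27 ± 0.18) and Wnt2 (4.14 ± 0.15). Nkd2 encodes a Wnt feedback inhibitor and Wnt2 a Wnt ligand. Of the genes that met the rule for naming, the lowest were Smoc2 (-4.93 ± 0.20), Irf7 (-4.82 ± 0.54), Eln (-4.63 ± 0.16), Usp18 (-4.55 ± 0.51), Ly6c1 (-4.55 ± 0.17), Add2 (-4.40 ± 0.18), Anxa8 (-4.29 ± 0.14) and Phf11d (-4.23 ± 0.41). Eln encodes elastin, and Irf7 and Usp18 belong to the interferon response. Acta2 (-0.84 ± 0.049) fell, Col1a1 (0.43 ± 0.037) and Postn (0.34 ± 0.035) rose, and Cthrc1 was at 0.16 ± 0.09 (adjusted p = 0.166).

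Of the 24 Wnt and beta-catenin target genes tested, 15 rose, 8 fell and 1 did not pass. The median was 1.22 (camera adjusted p = 0.00105), with Nkd2 at 4.68 ± 0.089, Notum at 4.55 ± 0.34, Axin2 at 3.74 ± 0.12 and Lef1 at 1.56 ± 0.11. Among 26 matrix protease and inhibitor genes, 15 rose, 4 fell and 7 did not pass. The median was 0.85 (camera adjusted p = 2.55e-07), with Mmp3 at 3.01 ± 0.12 and Mmp10 at 2.45 ± 0.18. All 30 tested interferon-stimulated genes fell. The median was -3.04 (camera adjusted p = 3.53e-17, and adjusted p = 0.0714 with an estimated correlation), with Ifi44 at -6.30 ± 0.59, Irf7 at -4.82 ± 0.54 and Usp18 at -4.55 ± 0.51. For the antigen presentation genes, 2 rose, 10 fell and 3 did not pass of 15 tested. The median was -0.82 (camera adjusted p = 0.00224, and adjusted p = 0.149 with an estimated correlation, adjusted over the list alone, 3 rose and 11 fell), with Tap1 at -2.83 ± 0.32 and Psmb8 at -3.07 ± 0.45. Across 19 adventitial fibroblast marker genes, 3 rose, 14 fell and 2 did not pass. The median was -1.33 (camera adjusted p = 6.05e-09), with Pcolce2 at -3.59 ± 0.12, Pi16 at -3.58 ± 0.23 and Ly6a at -3.08 ± 0.091. Among 20 TGFb and SMAD target genes, 3 rose, 14 fell and 3 did not pass. The median was -0.38 (camera adjusted p = 0.000653, adjusted over the list alone, 3 rose and 15 fell), with Nox4 at -2.33 ± 0.10, Ccn2 at -1.84 ± 0.063 and Inhba at 1.35 ± 0.051.

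For the contractile and myofibroblast genes, 4 rose, 13 fell and 5 did not pass of 22 tested. The median was -0.22 (camera adjusted p = 0.0019, and adjusted p = 0.197 with an estimated correlation, adjusted over the list alone, 4 rose and 14 fell), with Itga11 at -1.68 ± 0.05 and Acta2 at -0.84 ± 0.049. Against TGFb1, 1 rose and 17 fell (median -0.58, adjusted p = 0.0238 with an estimated correlation). Of the 27 fibrillar collagen and matrix genes tested, 12 rose, 10 fell and 5 did not pass. The median was 0.023 (mean -0.079, test directed upward, camera adjusted p = 0.723), with Eln at -4.63 ± 0.16, Fbn2 at 2.79 ± 0.083 and Ltbp2 at -2.71 ± 0.046. Against TGFb1, 12 rose and 13 fell (median -0.11). Across 22 collagen processing and crosslinking genes, 6 rose, 13 fell and 3 did not pass. The median was -0.12 (camera adjusted p = 0.0406, and adjusted p = 0.273 with an estimated correlation), with Lox at -1.63 ± 0.054 and Plod2 at -0.92 ± 0.04. Against TGFb1, 5 rose and 15 fell (median -0.25). Among 22 NF-kB feedback and target genes, 0 rose, 12 fell and 10 did not pass. The median was -0.24 (camera adjusted p = 0.0019, adjusted over the list alone, 0 rose and 13 fell), with Vcam1 at -1.61 ± 0.047, Tnfaip3 at -1.08 ± 0.084 and Nfkbia at -0.30 ± 0.077. For the chemokine genes, 1 rose, 8 fell and 6 did not pass of 15 tested. The median was -1.23 (camera adjusted p = 0.00156), with Cxcl12 at -4.12 ± 0.058, Cx3cl1 at -3.10 ± 0.083 and Cxcl10 at -2.77 ± 0.24. Against TGFb1, 2 rose and 9 fell (median -1.93). Across 25 cytokine and growth factor genes, 4 rose, 12 fell and 9 did not pass. The median was -0.67 (camera adjusted p = 0.00405, and adjusted p = 0.0675 with an estimated correlation), with Il6 at -2.31 ± 0.11 and Fgf7 at -1.96 ± 0.094. Against TGFb1, 5 rose and 15 fell (median -0.61, adjusted p = 0.0278 with an estimated correlation).

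All 28 tested cell cycle genes fell. The median was -0.70 (camera adjusted p = 2.18e-13), with Mcm5 at -1.24 ± 0.068 and Bub1 at -1.06 ± 0.074. Among 20 sterol synthesis genes, 1 rose and 19 fell. The median was -0.57 (camera adjusted p = 4.15e-09), with Nsdhl at -0.89 ± 0.058. For the secretory pathway and unfolded protein genes, 2 rose, 13 fell and 3 did not pass of 18 tested. The median was -0.33 (camera adjusted p = 0.000207, and adjusted p = 0.0706 with an estimated correlation), with Pdia6 at -0.58 ± 0.043 and Hspa5 at -0.55 ± 0.041. Against TGFb1, 1 rose and 14 fell (median -0.40, adjusted p = 0.0397 with an estimated correlation). For the alveolar fibroblast marker genes, 5 rose, 2 fell and 4 did not pass of 11 tested. The median was 0 (camera adjusted p = 0.198), with Wnt2 at 4.14 ± 0.15. Against TGFb1, 6 rose and 2 fell (median 0.23). Against TGFb1, Inhba was at 0.63, Nfkbia was at -0.58 and Postn was at 0.15.

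The median of the fibrillar collagen list was also below 0, at -0.002, with mitochondrial and rRNA genes left out, and that of the alveolar list lay at 0.21 by limma voom. In the edgeR test, 7019 of the 16197 genes tested passed (3369 higher, 3650 lower). Of them, 641 were at least 2-fold higher and 944 at least 2-fold lower. Of the lists, 16 of 30 passed the camera test (4 higher, 12 lower) and 8 passed with an estimated correlation. The acute phase, prostaglandin, adipogenic, glycolysis, p53 and ID family lists and all 5 lists of other cell types did not pass.

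Whether the CHIR effect differed with and without TGFb1 was tested as the interaction, and 6681 of the 16197 genes tested passed (3397 higher, 3284 lower). Of them, 1043 were at least 2-fold higher and 845 at least 2-fold lower. Of the 18 immediate early and heat shock genes tested, 15 were higher, 1 were lower and 2 did not pass. The median was 2.26 (camera adjusted p = 2.22e-10, and adjusted p = 0.0718 with an estimated correlation), with Fosb at 7.94 ± 0.30, Fos at 7.82 ± 0.27 and Egr1 at 5.09 ± 0.15. The CHIR effect on Fos was -7.66 without TGFb1 and 0.16 with it (adjusted p = 0.474). For an interaction, higher and lower refer to the CHIR effect with TGFb1 less that without it. Of the genes that met the rule for naming, the difference was highest for Fosb (7.94 ± 0.30), Fos (7.82 ± 0.27), Zfp36 (5.84 ± 0.18) and Osr2 (5.60 ± 0.17) and lowest for Col15a1 (-6.36 ± 0.13), Pdgfb (-4.91 ± 0.32), Lgr6 (-4.72 ± 0.30) and Hr (-4.72 ± 0.19). Among 28 cell cycle genes, 22 were higher, 0 were lower and 6 did not pass. The median was 1.72 (camera adjusted p = 2.01e-13, and adjusted p = 0.0619 with an estimated correlation), with Rrm2 at 2.64 ± 0.13 and Plk1 at 2.35 ± 0.14. For the interferon-stimulated genes, 0 were higher, 24 were lower and 6 did not pass of 30 tested. The median was -2.32 (camera adjusted p = 1.4e-11, and adjusted p = 0.192 with an estimated correlation, adjusted over the list alone, 0 were higher and 26 were lower), with Usp18 at -4.57 ± 0.75. Across 20 TGFb and SMAD target genes, 5 were higher, 13 were lower and 2 did not pass. The median was -0.65 (camera adjusted p = 0.00201, and adjusted p = 0.0619 with an estimated correlation), with Junb at 4.61 ± 0.13, Inhba at 1.86 ± 0.078 and Nox4 at -1.66 ± 0.17. Among 18 secretory pathway and unfolded protein genes, 0 were higher, 17 were lower and 1 did not pass. The median was -0.61 (camera adjusted p = 1.57e-09), with Hyou1 at -0.92 ± 0.06 and Hspa5 at -0.86 ± 0.058. Axin2 rose more with TGFb1 (1.83 ± 0.17), and Acta2 did not differ past the threshold (0.014 ± 0.069, adjusted p = 0.902). The difference of Col1a1 was 0.13 ± 0.052 (adjusted p = 0.0358) and did not pass with the DESeq2 Wald test (0.12), with RLE factors, with the stricter filter or with mitochondrial and rRNA genes left out, nor without CHIR replicate 1 or 2, DMSO replicate 2 or 3, TGFb1 + CHIR replicate 2, or TGFb1 + DMSO replicate 2 or 3.

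**Figure D5:**
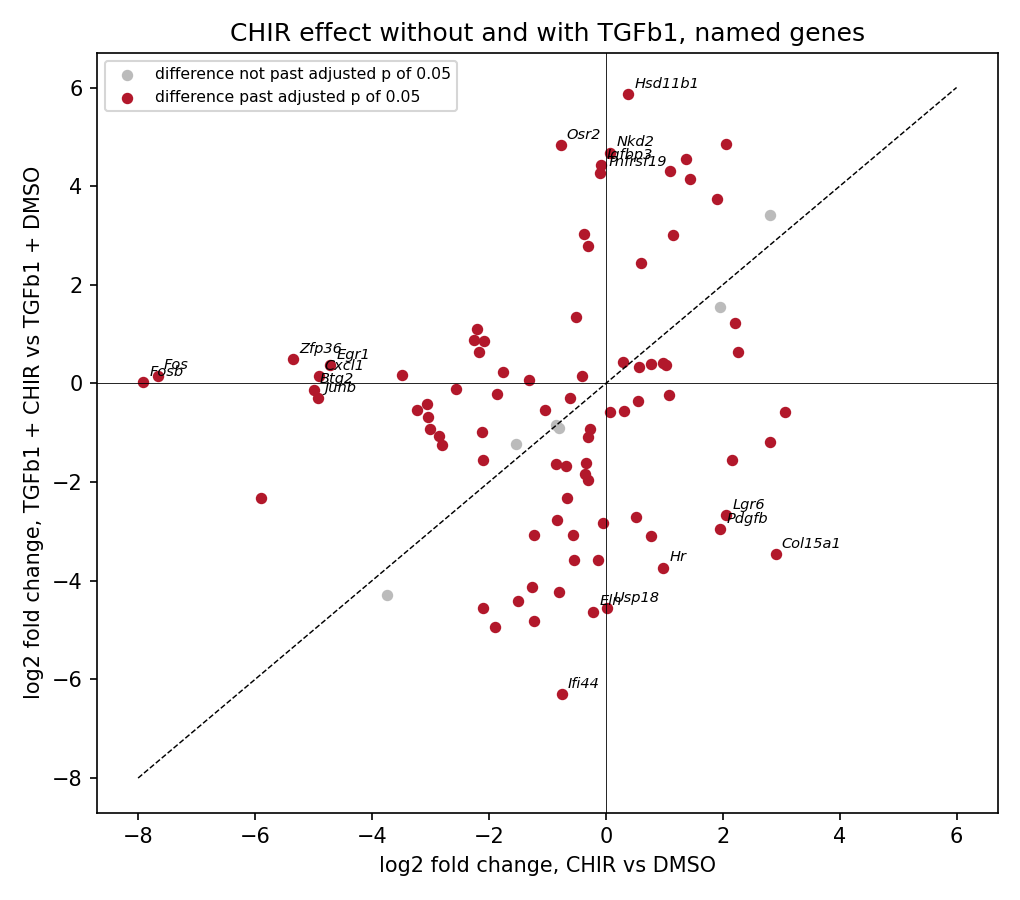
Log2 fold change of CHIR against DMSO without TGFb1 (x axis) and of TGFb1 + CHIR against TGFb1 + DMSO (y axis), with 1 point per named gene, red where the difference passed, and labels on genes whose effects differ most. Fos and Fosb lie at the far left near 0 on the y axis.

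TGFb1 + CHIR against CHIR showed the response to TGFb1 in cells given CHIR. C1qtnf3, a secreted C1q-like protein, rose 362-fold (8.50 ± 0.14), Dsp, a desmosome protein, 252-fold (7.97 ± 0.19) and Htr2b, a serotonin receptor, 226-fold (7.82 ± 0.18), and Anxa8 was listed at 0 in CHIR and thus at least 91.9-fold higher with TGFb1. The lowest were Tnxb (-7.95 ± 0.18), Ace (-7.88 ± 0.16), Efemp1 (-7.64 ± 0.069) and C3 (-7.55 ± 0.068). All 28 tested cell cycle genes rose. The median was 2.79 (camera adjusted p = 9.76e-15), with Rrm2 at 3.98 ± 0.10 and Bub1 at 3.43 ± 0.11. Among 27 fibrillar collagen and matrix genes, 21 rose and 6 fell. The median was 1.15 (camera adjusted p = 2.12e-05), with Tnc at 3.42 ± 0.084. For the acute phase and complement genes, 1 rose and 12 fell of 13 tested. The median was -2.66 (camera adjusted p = 2.82e-05). Across 30 interferon-stimulated genes, 3 rose, 19 fell and 8 did not pass. The median was -1.39, or -1.23 with genes at 0 in a group set to their bound (camera adjusted p = 0.00213, and adjusted p = 0.469 with an estimated correlation), with Parp14 at -3.54 ± 0.34. Among 24 Wnt and beta-catenin target genes, 19 rose and 5 fell. The median was 1.52 (camera adjusted p = 0.0006). In total 10715 of the 16197 genes tested passed (5477 higher, 5238 lower). Of them, 1744 were at least 2-fold higher and 2461 at least 2-fold lower. Of the lists, 18 of 30 passed the camera test (10 higher, 8 lower) and 8 passed with an estimated correlation.

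Of the 1520 genes at least 2-fold higher in TGFb1 than in DMSO, 685 (45.1%) were lower and 255 (16.8%) higher in TGFb1 + CHIR than in TGFb1 + DMSO, with a median log2 fold change of -0.33; of all genes tested, 22.5% were lower and 20.8% higher. Of the 2301 genes at least 2-fold lower in TGFb1 than in DMSO, 426 were lower and 532 higher (median 0.077).

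TGFb1 + IL1b against TGFb1 asked what IL1b adds to TGFb1. Chemokine, cytokine, acute phase and NF-kB target genes rose. Cxcl1 (gene ID ENSMUSG00000029380, GRCm38 chromosome 5, 90891241 to 90893115) rose 124-fold, from 0.833 ± 0.418 to 107 ± 18.3 CPM (6.95 ± 0.22, adjusted p = 1.17e-15), Il6 3.45-fold (1.79 ± 0.086) and Nos2, the inducible nitric oxide synthase, 203-fold (7.67 ± 0.15). Others among the highest were Prg4 (3.08 ± 0.11), Dhrs9 (2.97 ± 0.19), Ccl2 (2.93 ± 0.091), C3 (2.84 ± 0.053), Gfra2 (2.63 ± 0.11) and Zc3h12a (2.63 ± 0.084); Prg4 encodes the lubricant lubricin and Zc3h12a an RNase that limits inflammation. C1qtnf3 (gene ID ENSMUSG00000058914, GRCm38 chromosome 15, 10952332 to 10980150) fell most (-3.58 ± 0.11), followed by Adamts15 (-3.09 ± 0.33), Aspn (-3.09 ± 0.17), Eln (-2.87 ± 0.13), Mfap4 (-2.47 ± 0.15), Ogn (-2.13 ± 0.085), Ccn3 (-2.01 ± 0.082) and Fhod3 (-1.95 ± 0.15), of which Aspn, Ogn and Mfap4 encode small matrix proteins. Acta2 (-0.41 ± 0.049), Col1a1 (-0.13 ± 0.037) and Cthrc1 (-0.56 ± 0.09) fell, though Col1a1 did not pass without TGFb1 replicate 3 (-0.10). Against TGFb1 + DMSO none of these 3 passed, with Acta2 at -0.018 and Cthrc1 at -0.21. Postn (0.28 ± 0.035) and Nfkbia (0.98 ± 0.07) rose, and Lef1 was at 0.12 ± 0.11 (adjusted p = 0.467), though it passed against TGFb1 + DMSO (0.34).

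Of the 22 NF-kB feedback and target genes tested, 19 rose, 0 fell and 3 did not pass. The median was 0.61 (camera adjusted p = 1.42e-12), with Zc3h12a at 2.63 ± 0.084, Nfkbiz at 1.94 ± 0.084 and Sod2 at 1.51 ± 0.057. Among 15 chemokine genes, 9 rose, 2 fell and 4 did not pass. The median was 1.71 (camera adjusted p = 8.8e-05), with Cxcl1 at 6.95 ± 0.22 and Ccl2 at 2.93 ± 0.091, and Cxcl5 at least 191-fold higher because it was listed at 0 in TGFb1. For the cytokine and growth factor genes, 20 rose, 1 fell and 4 did not pass of 25 tested. The median was 1.11 (camera adjusted p = 1.06e-11, adjusted over the list alone, 20 rose and 2 fell), with Tslp at 2.79 ± 0.37 and Il6 at 1.79 ± 0.086; Csf2 was at least 96.9-fold higher and Il1a at least 40.9-fold higher. Across 13 acute phase and complement genes, 9 rose, 1 fell and 3 did not pass. The median was 1.03 (camera adjusted p = 4.8e-07, adjusted over the list alone, 10 rose and 1 fell), with Saa3 at 6.41 ± 0.36, Steap4 at 4.69 ± 0.37 and Hp at 3.92 ± 0.30. Against TGFb1 + DMSO, 9 rose and 1 fell (median 1.61). Among 14 prostaglandin and oxidative response genes, 8 rose, 2 fell and 4 did not pass. The median was 0.20 (camera adjusted p = 0.00156), with Nos2 at 7.67 ± 0.15 and Ptgs2 at 1.78 ± 0.09. All 18 tested ATF4, serine and proline synthesis genes rose. The median was 0.73 (camera adjusted p = 8.56e-18), with Ddit3 at 1.63 ± 0.088 and Psph at 1.10 ± 0.069. Of the 30 interferon-stimulated genes tested, 27 rose, 0 fell and 3 did not pass. The median was 0.99 (camera adjusted p = 2.16e-07, and adjusted p = 0.306 with an estimated correlation, adjusted over the list alone, 28 rose and 0 fell), with Gbp5 at 1.80 ± 0.33. Against TGFb1 + DMSO, 11 rose and 0 fell (median 0.52).

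For the antigen presentation genes, 11 rose, 0 fell and 4 did not pass of 15 tested. The median was 0.47 (camera adjusted p = 6.1e-05, and adjusted p = 0.0672 with an estimated correlation), with Cd74 at 0.74 ± 0.10. Against TGFb1 + DMSO, 8 rose and 0 fell (median 0.31). Among 22 contractile and myofibroblast genes, 0 rose, 16 fell and 6 did not pass. The median was -0.34 (camera adjusted p = 4.13e-08, adjusted over the list alone, 0 rose and 18 fell), with Myl9 at -0.99 ± 0.061 and Lmod1 at -0.94 ± 0.085. Against TGFb1 + DMSO, 4 rose and 8 fell (median -0.031, camera adjusted p = 0.552, adjusted p = 0.863 with an estimated correlation). For the fibrillar collagen and matrix genes, 5 rose, 15 fell and 7 did not pass of 27 tested. The median was -0.12 (camera adjusted p = 0.0205, and adjusted p = 0.116 with an estimated correlation), with Eln at -2.87 ± 0.13, Col5a3 at 1.35 ± 0.042 and Thbs1 at -1.29 ± 0.041. Against TGFb1 + DMSO, 8 rose and 10 fell (median -0.063, camera adjusted p = 0.552). Across 6 mural and smooth muscle marker genes, 1 rose, 4 fell and 1 did not pass. The median was -0.65 (camera adjusted p = 0.00835), with Pdgfrb at -0.93 ± 0.04 and Mcam at -1.16 ± 0.11. Against TGFb1 + DMSO, 1 rose and 4 fell (median -0.66, camera adjusted p = 0.0518, adjusted p = 0.123 with an estimated correlation). Of the 20 TGFb and SMAD target genes tested, 6 rose, 9 fell and 5 did not pass. The median was -0.08 (mean 0.008, test directed downward, camera adjusted p = 0.505), with Timp1 at 1.18 ± 0.043, Inhba at 1.12 ± 0.051 and Tgfb3 at -1.08 ± 0.048. Against TGFb1 + DMSO, 8 rose and 7 fell (median -0.0063). Against TGFb1 + DMSO, Tslp was at 1.83, Gbp5 was at 1.03, Cd74 was at 1.25, Myl9 was at -0.54, Lmod1 was at -0.27 and Inhba was at 1.84.

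In the edgeR test, 5600 of the 16197 genes tested passed (2787 higher, 2813 lower). Of them, 537 were at least 2-fold higher and 307 at least 2-fold lower. Of the lists, 13 of 30 passed the camera test (8 higher, 5 lower) and 8 passed with an estimated correlation. The control here is TGFb1 without DMSO, and it is also the control of the TNF comparison.

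TGFb1 + TNF against TGFb1 asked what TNF adds to TGFb1. Matrix genes fell and NF-kB target and cytokine genes rose. Col1a1 fell 2.45-fold (-1.29 ± 0.038, adjusted p = 4.63e-32), Acta2 2.65-fold (-1.41 ± 0.05), Cthrc1 3.15-fold (-1.66 ± 0.10) and Ly6a 3.24-fold (-1.70 ± 0.075). Of genes meeting the naming rule, Mmp9, a gelatin-cutting protease (gene ID ENSMUSG00000017737, GRCm38 chromosome 2, 164940780 to 164955850), rose most, from 8.38 ± 1.2 to 383 ± 24.3 CPM (5.53 ± 0.084). Next were Prg4 (4.91 ± 0.11), Abcb1a (3.81 ± 0.078), Hmga2 (3.79 ± 0.10), Igfbp5 (3.78 ± 0.12), Gch1 (3.51 ± 0.17) and Dhrs9 (3.48 ± 0.19). Hmga1 met the rule but appears to lack shared reads. C1qtnf3 fell most, from 82.7 ± 0.639 to 0.291 ± 0.218 CPM (-8.11 ± 0.18), followed by Ccn5 (-7.52 ± 0.14), Fndc1 (-7.30 ± 0.19), Mfap4 (-6.04 ± 0.23), Aspn (-5.83 ± 0.23), Cyp1b1 (-5.75 ± 0.065), Adamts15 (-5.60 ± 0.48) and Serpinb1a (-5.57 ± 0.13). Lef1 (0.96 ± 0.11) rose while Axin2 (-2.45 ± 0.18) fell.

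Of the 27 fibrillar collagen and matrix genes tested, 3 rose, 22 fell and 2 did not pass. The median was -1.04 (camera adjusted p = 2.31e-09, adjusted over the list alone, 4 rose and 22 fell), with Col11a1 at -3.33 ± 0.063, Col12a1 at -2.51 ± 0.041 and Eln at -3.36 ± 0.13. Among 22 collagen processing and crosslinking genes, 2 rose, 18 fell and 2 did not pass. The median was -0.49 (camera adjusted p = 4.35e-07), with P4ha3 at -1.83 ± 0.072 and Pcolce at -1.36 ± 0.039. Against TGFb1 + DMSO, 3 rose and 17 fell (median -0.33, adjusted p = 0.0701 with an estimated correlation). For the contractile and myofibroblast genes, 2 rose, 18 fell and 2 did not pass of 22 tested. The median was -0.83 (camera adjusted p = 1.55e-07), with Lmod1 at -3.80 ± 0.11, Itga11 at -3.56 ± 0.056 and Myl9 at -3.19 ± 0.069. Against TGFb1 + DMSO, 3 rose and 14 fell (median -0.58, adjusted p = 0.162 with an estimated correlation). Across 6 mural and smooth muscle marker genes, 1 rose and 5 fell. The median was -1.86 (camera adjusted p = 0.00663), with Pdgfrb at -2.04 ± 0.042 and Notch3 at -2.17 ± 0.084. Against TGFb1 + DMSO, 1 rose and 4 fell (median -1.75, adjusted p = 0.0701 with an estimated correlation). Of the 11 ID family and BMP target genes tested, 1 rose, 8 fell and 2 did not pass. The median was -1.25 (camera adjusted p = 0.00193), with Id3 at -2.37 ± 0.093 and Smad6 at -1.65 ± 0.11. Against TGFb1 + DMSO, 1 rose and 8 fell (median -1.06, adjusted p = 0.0544 with an estimated correlation). Among 22 NF-kB feedback and target genes, 14 rose, 3 fell and 5 did not pass. The median was 0.71 (camera adjusted p = 6.15e-05, adjusted over the list alone, 15 rose and 3 fell), with Relb at 1.86 ± 0.079 and Nfkbie at 1.46 ± 0.089.

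For the cytokine and growth factor genes, 18 rose, 1 fell and 6 did not pass of 25 tested. The median was 1.14, or 1.10 with genes at 0 in a group set to their bound (camera adjusted p = 1.97e-05, adjusted over the list alone, 18 rose and 2 fell), with Areg at 5.05 ± 0.33 and Tslp at 4.25 ± 0.34, and Csf2 at least 253-fold higher because it was listed at 0 in TGFb1. Across 15 chemokine genes, 6 rose, 3 fell and 6 did not pass. The median was 0.56, or 0.21 with genes at 0 in a group set to their bound (camera adjusted p = 0.354), with Cxcl1 at 3.10 ± 0.28, Ccl5 at 2.92 ± 0.21 and Cxcl12 at -1.98 ± 0.051. Among 13 acute phase and complement genes, 2 rose, 5 fell and 6 did not pass. The median was -0.17 (mean 0.20, test directed downward, camera adjusted p = 0.414), with C4b at -3.78 ± 0.11, Saa3 at 3.23 ± 0.45 and C3 at 1.61 ± 0.052. Against TGFb1 + DMSO, 2 rose and 4 fell (median 0.41). For the interferon-stimulated genes, 29 rose, 0 fell and 1 did not pass of 30 tested. The median was 1.27 (camera adjusted p = 6.25e-06, and adjusted p = 0.357 with an estimated correlation), with Ifi44 at 2.68 ± 0.28 and Oas3 at 3.40 ± 0.54. Against TGFb1 + DMSO, 21 rose and 0 fell (median 0.68). Of the 15 antigen presentation genes tested, 11 rose, 1 fell and 3 did not pass. The median was 0.74 (camera adjusted p = 0.00256, and adjusted p = 0.159 with an estimated correlation), with Cd74 at 1.15 ± 0.10. Against TGFb1 + DMSO, 9 rose and 1 fell (median 0.40). All 18 tested ATF4, serine and proline synthesis genes rose. The median was 0.97 (camera adjusted p = 6.34e-11, and adjusted p = 0.0718 with an estimated correlation), with Ddit3 at 1.83 ± 0.088 and Psph at 1.67 ± 0.069.

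Among 19 glycolysis and hypoxia genes, 3 rose, 13 fell and 3 did not pass. The median was -0.65 (camera adjusted p = 0.00278, and adjusted p = 0.254 with an estimated correlation, adjusted over the list alone, 3 rose and 14 fell), with Adm at -4.47 ± 0.20 and Pfkfb3 at -2.31 ± 0.083. Of the 19 adventitial fibroblast marker genes tested, 4 rose, 12 fell and 3 did not pass. The median was -0.59 (camera adjusted p = 0.00663, and adjusted p = 0.0987 with an estimated correlation), with Col14a1 at -2.96 ± 0.053 and Cd34 at 2.66 ± 0.12. For the matrix protease and inhibitor genes, 6 rose, 15 fell and 5 did not pass of 26 tested. The median was -0.71 (camera adjusted p = 0.00438, and adjusted p = 0.0987 with an estimated correlation), with Mmp9 at 5.53 ± 0.084 and Adamts9 at -3.20 ± 0.10. Against TGFb1 + DMSO, 6 rose and 17 fell (median -1.09). Across 20 TGFb and SMAD target genes, 8 rose, 10 fell and 2 did not pass. The median was -0.18 (camera adjusted p = 0.687), with Tgfbi at -2.23 ± 0.057 and Inhba at 1.90 ± 0.052. Against TGFb1 + DMSO, 9 rose and 9 fell (median 0.0072). Against TGFb1 + DMSO, Ifi44 was at 1.77.

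In the edgeR test, 9161 of the 16197 genes tested passed (4489 higher, 4672 lower). Of them, 1085 were at least 2-fold higher and 1541 at least 2-fold lower. Of the lists, 16 of 30 passed the camera test (6 higher, 10 lower) and 7 passed with an estimated correlation. Of the endothelial markers, Cdh5 rose (4.15 ± 0.56) and Kdr rose (0.99 ± 0.19, or 0.60 against TGFb1 + DMSO), at 4.54 ± 0.212 and 6.32 ± 0.414 CPM, but the list did not pass (camera adjusted p = 0.385).

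TGFb1 + IL1b against TGFb1 + TNF compared both cytokines directly. Matrix and acute phase genes were higher with IL1b: Col3a1, a fibrillar collagen chain, was 4.02-fold higher (2.01 ± 0.038) and Saa3 9.06-fold (3.18 ± 0.25). Cxcl1 was 14.5-fold higher (3.86 ± 0.15) and Il6 2.71-fold (1.44 ± 0.084). The highest with IL1b were Fndc1 (6.46 ± 0.20), Ccn5 (5.61 ± 0.17), Cyp1b1 (5.42 ± 0.065) and Serpinb1a (4.94 ± 0.14), and Mmp9 (-3.78 ± 0.072), Add2 (-2.95 ± 0.079) and Hmga2 (-2.84 ± 0.092) were highest with TNF. Of the 27 fibrillar collagen and matrix genes tested, 23 were higher, 3 were lower and 1 did not pass. The median was 0.93 (camera adjusted p = 4.69e-11), with Col12a1 at 2.46 ± 0.041 and Col11a1 at 2.12 ± 0.062. Among 22 collagen processing and crosslinking genes, 18 were higher, 3 were lower and 1 did not pass. The median was 0.58 (camera adjusted p = 8.42e-09), with P4ha3 at 1.68 ± 0.072. For the acute phase and complement genes, 11 were higher, 0 were lower and 2 did not pass of 13 tested. The median was 1.95 (camera adjusted p = 4.77e-08), with Steap4 at 3.70 ± 0.32 and Hp at 3.43 ± 0.27. Across 11 ID family and BMP target genes, 7 were higher, 0 were lower and 4 did not pass. The median was 0.80 (camera adjusted p = 0.000921, adjusted over the list alone, 8 were higher and 0 were lower), with Smad9 at 2.23 ± 0.22 and Id3 at 1.91 ± 0.10. Among 19 adventitial fibroblast marker genes, 13 were higher, 4 were lower and 2 did not pass. The median was 0.78 (camera adjusted p = 0.000281), with Col14a1 at 2.18 ± 0.054 and Cd34 at -1.77 ± 0.11. For the NF-kB feedback and target genes, 8 were higher, 11 were lower and 3 did not pass of 22 tested. The median was -0.15 (camera adjusted p = 0.574), with Zc3h12a at 2.74 ± 0.084 and Nfkbiz at 2.06 ± 0.084. In total 7706 of the 16197 genes tested passed (4008 higher, 3698 lower). Of them, 1116 were at least 2-fold higher and 359 at least 2-fold lower. Of the lists, 15 of 30 passed the camera test (13 higher, 2 lower) and 5 passed with an estimated correlation.

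Across genes, which are not independent replicates, the log2 fold changes of both cytokines against TGFb1 had a Pearson r of 0.648 and a covariance of 0.499. Cxcl1, Prg4 and Dhrs9 were among the 2057 genes higher with both cytokines, C1qtnf3, Aspn and Mfap4 among the 2178 lower with both, and 326 genes moved in opposite directions; independent calls would give 772 and 811. The shared control alone raises r: in 20 simulations of unchanged groups against the same controls r averaged 0.525 (0.496 to 0.548), with a covariance of 0.0599. With TGFb1 as the control of IL1b and TGFb1 + DMSO as that of TNF, r was 0.52, the covariance 0.409 and the calls in the same direction 4122, with 342 opposite. With these controls exchanged, r was 0.498, the covariance 0.405 and these calls 4249, and the opposite calls were 591.

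Of the 1307 genes at least 2-fold higher in TGFb1 + DMSO than in DMSO, 288 were lower and 351 higher with IL1b, and 454 were lower and 472 higher with TNF. The 2224 genes at least 2-fold lower in TGFb1 + DMSO numbered 411 lower and 307 higher with IL1b, and 870 lower (39.1%) and 308 higher with TNF (median -0.45). Of all genes tested, 17.4% were lower and 17.2% higher with IL1b, and 28.8% and 27.7% with TNF. C3, a gene lowered by TGFb1, rose with IL1b and with TNF, and Adamts15, also lowered, fell further with both.

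TGFb1 + DMSO against TGFb1 tested the solvent in cells given TGFb1. Contractile and matrix genes were slightly lower with the solvent: Acta2 fell 1.31-fold (-0.39 ± 0.049, adjusted p = 1.07e-06) and Cnn1, a smooth muscle calponin, 1.47-fold (-0.56 ± 0.063), while Mmp13 rose 1.94-fold (0.96 ± 0.11). The others among the highest were Abi3bp (1.52 ± 0.31), Adamts15 (0.90 ± 0.18) and Lbp (0.82 ± 0.14), and among the lowest were Kcnab1 (-1.09 ± 0.20) and Aqp1 (-1.08 ± 0.24). Of the 22 contractile and myofibroblast genes tested, 0 rose, 16 fell and 6 did not pass. The median was -0.32 (camera adjusted p = 3.6e-21, adjusted over the list alone, 0 rose and 18 fell), with Lmod1 at -0.67 ± 0.084 and Smtn at -0.48 ± 0.046. Among 27 fibrillar collagen and matrix genes, 1 rose, 12 fell and 14 did not pass. The median was -0.13 (camera adjusted p = 2.28e-07, adjusted over the list alone, 2 rose and 15 fell), with Thbs1 at -0.42 ± 0.04 and Col8a1 at -0.40 ± 0.055. For the collagen processing and crosslinking genes, 0 rose, 9 fell and 13 did not pass of 22 tested. The median was -0.14 (camera adjusted p = 1.52e-08, adjusted over the list alone, 1 rose and 15 fell), with Loxl3 at -0.36 ± 0.053. Across 19 adventitial fibroblast marker genes, 1 rose, 9 fell and 9 did not pass. The median was -0.24 (camera adjusted p = 5.5e-07, adjusted over the list alone, 2 rose and 13 fell), with Col15a1 at -0.60 ± 0.076. Among 25 cytokine and growth factor genes, 0 rose, 8 fell and 17 did not pass. The median was -0.26 (camera adjusted p = 6.38e-05, adjusted over the list alone, 0 rose and 13 fell), with Hgf at -0.48 ± 0.079. For the Wnt and beta-catenin target genes, 1 rose, 6 fell and 17 did not pass of 24 tested. The median was -0.13 (camera adjusted p = 0.00395, adjusted over the list alone, 2 rose and 6 fell), with Ccnd1 at -0.65 ± 0.074. Among 30 interferon-stimulated genes, 2 rose, 0 fell and 28 did not pass. The median was 0.42 (camera adjusted p = 9.22e-07, and adjusted p = 0.353 with an estimated correlation, adjusted over the list alone, 6 rose and 0 fell), with Ifit2 at 0.39 ± 0.068. In the edgeR test, 993 of the 16197 genes tested passed (378 higher, 615 lower). Of them, 18 were at least 2-fold higher and 35 at least 2-fold lower. Of the lists, 13 of 30 passed the camera test (2 higher, 11 lower) and 6 passed with an estimated correlation. Without TGFb1 replicate 1 the count was 646, a fall by more than 1.5 times.

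Among 3 epithelial marker genes, 0 rose, 1 fell and 2 did not pass in TGFb1 + CHIR against TGFb1 + DMSO. The median was 0.15 (mean -0.20, test directed upward, camera adjusted p = 0.983, adjusted over the list alone, 1 rose and 1 fell). Against TGFb1, 1 rose and 1 fell (median 0.36). Of the 7 endothelial marker genes tested, 2 rose, 2 fell and 3 did not pass in the same comparison. The median was -0.32 (mean -0.11, test directed upward, camera adjusted p = 0.904). For the immune cell marker genes, 2 rose, 0 fell and 3 did not pass of 5 tested in TGFb1 + IL1b against TGFb1. The median was 0.80, or 0.58 with genes at 0 in a group set to their bound (camera adjusted p = 0.0657, adjusted over the list alone, 3 rose and 0 fell), with Cd14 at 0.80 ± 0.16. All 3 tested mesothelial marker genes fell in CHIR against DMSO. The median was -6.41, or -3.32 with genes at 0 in a group set to their bound (camera adjusted p = 0.0193, and adjusted p = 0.109 with an estimated correlation).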

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

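The tests of heat stress, of CHIR with TGFb1, of immune cells and other controls for the interferon-stimulated genes, of leaving out 1 library, and of other splits were chosen after the result was seen; those of GC content and of a weaker TGFb1 response were chosen before. The results here stand out because the effect of CHIR differed with and without TGFb1 in a test of the difference itself: 6681 genes passed, and the values below are the effect with TGFb1 less that without it, in log2. Fits of only these 4 groups gave 6736 genes, the highest of the other splits gave 2036, and 1 of 100 splits, the real one, gave as many. The other splits mixed all 4 groups and so also broke the effects of TGFb1 and of CHIR themselves. They therefore cannot decide whether the interaction alone arose by chance.

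Among immediate early and mRNA decay genes the values were Fosb 7.94, Fos 7.82, Zfp36 5.84, Btg2 4.87, Junb 4.61 and Egr1 5.09. For cytokines, chemokines and inflammatory regulators they were Il6 3.58, Cxcl1 5.07, Lif 3.30, Tslp 2.81, Ptx3 3.13, Saa3 3.41 and Ptgs2 1.13, and Nfkbia 0.32, Nfkbiz 3.64, Zc3h12a 1.65, Tnfaip3 -0.78, Vcam1 -1.28, Cxcl12 -2.86, Cx3cl1 -3.88, Cxcl10 -1.94 and Fgf7 -1.66. Cell cycle genes gave Mki67 2.09, Plk1 2.35, Rrm2 2.64, Ccnb1 2.68, Mcm5 1.56, Bub1 1.80 and Ccnd1 0.54. Wnt pathway genes gave Axin2 1.83, Nkd2 4.61, Notum 3.19, Tnfrsf19 4.38, Wnt2 2.70 and Lgr6 -4.72. Interferon and antigen presentation genes gave Irf7 -3.58, Usp18 -4.57, Ifi44 -5.54, Phf11d -3.44, Tap1 -2.78 and Psmb8 -2.50. Matrix genes and their processing gave Col1a1 0.13, Postn -0.23, Cthrc1 0.57, Col12a1 2.94, Col8a1 2.46, Col15a1 -6.36, Eln -4.41, Fbn2 3.10, Ltbp2 -3.23, Smoc2 -3.03, Lox -0.78 and Plod2 -0.64. Proteases gave Mmp13 2.80, Mmp3 1.85, Mmp10 1.84, Adamts15 3.22 and Plau 1.39. TGFb targets and contractile genes gave Ccn2 -1.48, Nox4 -1.66, Inhba 1.86, Fhl2 1.99 and Itga11 -0.99. Surface and adventitial markers gave Ly6a -1.85, Ly6c1 -2.45, Pi16 -3.03 and Pcolce2 -3.45. Growth factor and receptor genes gave Igfbp3 4.52, Igfbp5 -3.64, Pdgfb -4.91, Megf10 -3.98 and Olr1 -3.70. Sterol, folding and redox genes gave Mvk 0.51, Atf6 -0.38, Hyou1 -0.92, Pdia6 -0.66, Hspa5 -0.86 and Gclc -1.32, and mitochondrial genes mt-Nd4 -0.66 and mt-Cytb -0.56. The others were Hsd11b1 5.48, Osr2 5.60, Hr -4.72, Mamdc2 -1.64, Mmd -0.99 and Add2 -2.90. The Col1a1 difference did not pass with the DESeq2 Wald test, at 0.12.

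By list, the median differences were -0.65 for TGFb and SMAD target genes, 0.72 for Wnt and beta-catenin target genes, 0.72 for matrix protease and inhibitor genes, -2.32 for interferon-stimulated genes, -0.80 for antigen presentation genes, -0.20 for adventitial fibroblast marker genes, 1.72 for cell cycle genes, -0.40 for adipogenic and lipid genes, 0.52 for ATF4, serine and proline synthesis genes, -0.61 for secretory pathway and unfolded protein genes, 2.26 for immediate early and heat shock genes and -0.59 for mitochondrially encoded genes. With an estimated correlation, only the secretory pathway list passed.

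Immediate early genes, among them Fos and Egr1, were lower in CHIR than in DMSO. Their median of 0.16 with TGFb1 cannot decide if CHIR acts alike without it, as DMSO may be raised. Handling stress of the DMSO cultures may contribute and cannot be told apart here, since the heat shock genes had a median of -0.77 with members both past and short of the threshold. An effect of CHIR in cells without TGFb1 stays open too.

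All 30 interferon-stimulated genes, such as Irf7 and Usp18, were lower in TGFb1 + CHIR than in TGFb1 + DMSO, a list call that did not pass with an estimated correlation. Transcripts of immune cells are argued against, as the summed immune markers were 1.06 times as high and the interferon-stimulated genes 3.9 times. A high level in TGFb1 + DMSO alone is argued against, as 30 of 30 were also lower than in TGFb1. Loss of a TGFb1-associated rise alone stays open: against CHIR the list (median -1.39) did not pass with an estimated correlation. A lowering by CHIR with TGFb1 is a hypothesis.

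Between TGFb1 + DMSO and TGFb1, 993 genes differed, among them Acta2 and Mmp13. GC content and transcript length are argued against, since 1069 genes differed after a correction, 810 of them shared. A lone library is argued against as the whole cause, since 646 genes remained in number without TGFb1 replicate 1. A weaker response throughout is argued against: of genes raised by TGFb1 in CHIR-treated cells 169 were lower and 20 higher, but of lowered genes 102 were higher and 109 lower, and the smaller of both ratios was 0.936. An effect of the solvent may remain, and a shared day of harvest is not given in the labels.

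For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave as many genes as any in 1 of them. Real values and the highest of the others were 9475 and 0 for TGFb1 + DMSO against DMSO, 7428 and 0 for CHIR against DMSO, 6963 and 0 for TGFb1 + CHIR against TGFb1 + DMSO, 10558 and 0 for TGFb1 + CHIR against CHIR, 5718 and 0 for TGFb1 + IL1b against TGFb1, 8463 and 0 for TGFb1 + TNF against TGFb1, 7763 and 0 for TGFb1 + IL1b against TGFb1 + TNF, 868 and 1 for TGFb1 + DMSO against TGFb1, 665 and 0 for TGFb1-raised genes under CHIR, 314 and 0 for TGFb1-raised genes under IL1b and 442 and 0 for TGFb1-raised genes under TNF.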

How the results depend on the processing

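All alternatives were planned except leaving out replicates for the IL1b and TNF overlap, chosen after the result was seen. Counts of genes, with the range under the other settings and then the range when 1 library was left out, were 10037 (9475 to 10292, 9496 to 9737) for TGFb1 + DMSO against DMSO, 7260 (6961 to 7443, 6427 to 6772) for CHIR against DMSO, 7019 (6703 to 7383, 6246 to 6500) for TGFb1 + CHIR against TGFb1 + DMSO, 10715 (10100 to 10688, 10063 to 10374) for TGFb1 + CHIR against CHIR, 5600 (5247 to 6366, 4718 to 5060) for IL1b, 9161 (8463 to 9233, 8602 to 8774) for TNF, 7706 (7376 to 7821, 6858 to 7182) for IL1b against TNF and 6681 (6382 to 6769, 6148 to 6481) for the interaction. They were 685 (655 to 717, 644 to 717), 288 (280 to 310, 244 to 295) and 454 (438 to 468, 431 to 465) for TGFb1-raised genes lower under CHIR, IL1b and TNF, and 4235 (3687 to 4249, 3693 to 4189) for the overlap. The solvent comparison gave 993 (868 to 1254, 646 to 884), the lowest without TGFb1 replicate 1, and the cause was not tested. Of its genes changed at least 2-fold, 53 passed, 33 without TGFb1 replicate 1 and 33 with only the groups of the comparison in the fit. List calls over all comparisons numbered 134 with the preset correlation, 60 with an estimated correlation, which widens the test, and 211 with fry, which asks a different question. Of up to 1126 values of named genes, 13 lost their call with DESeq2, 29 with limma voom, 13 with no filter and 19 with only the groups of the comparison in the fit. With the other TGFb1 control, 23 lost it for IL1b or TNF and 5 for TGFb1 + DMSO against DMSO or TGFb1 + CHIR against TGFb1 + DMSO; with IL1b, Ly6a (0.1889), Ly6c1 (0.2343) and Lpl (-0.1062) changed sign. Each named value was refitted several times with 1 library left out. Over all these refits, a call was lost in 328, gained in 2 and unchanged in 7176. Depth limits the genes at 0 in a group, whose folds are bounds.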

Other observations

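The genes in this part were chosen after their values were seen, and no explanation was tested for them. Values in parentheses are log2 fold changes from edgeR ± SE derived from its F statistic, n = 3 per group. With TNF added to TGFb1, Pdgfra (-2.47 ± 0.045), Pdgfrb (-2.04 ± 0.042), Tgfbr2 (-2.33 ± 0.043) and Tgfbr3 (-1.40 ± 0.071) fell, and with IL1b Pdgfra (-1.01 ± 0.043), Pdgfrb (-0.93 ± 0.04) and Tgfbr2 (-1.12 ± 0.041) fell while Tgfbr3 (0.62 ± 0.064) rose. Tgfbr1 passed in neither, with an adjusted p of 0.973 for IL1b and 0.578 for TNF. Igf1 stood at 23 ± 1.02 CPM (mean ± SD) in TGFb1 and 0.651 ± 0.274 in TGFb1 + TNF. Igfbp3 stood at 4740 ± 254 CPM in TGFb1 + CHIR and at 220 ± 12.6 in TGFb1 + DMSO, and Igfbp5 at 58.6 ± 2.85 in DMSO and 490 ± 34.5 in CHIR.

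In TGFb1 + DMSO against DMSO, Dcn (-3.29 ± 0.044), Ogn (-3.39 ± 0.076) and Prelp (-3.99 ± 0.055) fell. With CHIR alone Dcn rose and the others fell: Dcn (0.57 ± 0.04), Ogn (-1.34 ± 0.069) and Prelp (-0.99 ± 0.048). The basement membrane genes Col4a1 (0.48 ± 0.041) and Col4a2 (0.49 ± 0.039) rose with CHIR alone, and Col4a1 (-1.89 ± 0.043), Col4a2 (-1.77 ± 0.041) and Nid1 (-0.50 ± 0.038) fell with CHIR in the presence of TGFb1. The genes Sfrp1 (0.99 ± 0.10), Fzd1 (1.98 ± 0.047), Wnt9a (1.80 ± 0.092) and Grem1 (1.11 ± 0.052) rose with CHIR in the presence of TGFb1, and Sfrp1 (-3.32 ± 0.13) and Fzd1 (-2.79 ± 0.053) fell with TNF; Sfrp1 encodes a secreted Wnt antagonist and Grem1 a BMP antagonist. Fos stood at 1520 ± 112 CPM in DMSO, 7.45 ± 0.842 in CHIR and 129 ± 29.4 in TGFb1.

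Several genes with near-identical copies elsewhere in the genome held few counts for their usual level in cells. Gapdh ran from 0 to 0.258 CPM over the libraries, Tpt1 from 1.47 to 3.99, Pgk1 from 0.925 to 13.3 and mt-Co2 from 1.34 to 5.74, while mt-Co1 ran from 369 to 1380. How reads with more than 1 match were counted is not given in the sources used here, and no test was run.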
